A study of Meleagris gallopavo with 12 samples.

How the data were processed

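The series held 12 samples of premammillary nucleus, a cell group at the back of the hypothalamus, from adult turkey hens. Each sample was a pool of tissue from 6 hens, per the labels, and the groups were short-day photosensitive (SDPS), long-day photosensitive (LDPS) and long-day photorefractory (LDPR) hens, with 4 pools each. Total RNA was turned into labelled cDNA by an indirect labelling kit, per the labels' protocols, with Alexa Fluor 555 in 2 pools of each group and Alexa Fluor 647 in the other 2. A pair of pools, always of different groups, shared each of the 6 arrays, so that the 3 groups formed a loop with 2 arrays per pair of groups, 1 in each dye orientation. The deposited files of the pair of samples on an array held identical values, so each array was read once.

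Spot intensity was estimated by the authors with BlueFuse for Microarrays 3.6 (build 7145), per the file headers, from images taken at 532 and 635 nm. The deposited intensity is 1 amplitude per spot and channel, with no separate background column, so no further background was removed. The deposited confidence score of each spot runs up to 1, per the file headers, and spots with a confidence score under 0.1 were treated as missing. The design named only the scanner's own bad flags, and this threshold was chosen once the files showed how spots were graded. The authors' deposited value table holds log2 intensities per sample, with 20478 probes and column medians from 7.435 to 7.578. In 12 of 12 columns the log2 value lay closer to the channel of the sample's own dye, which settled direction and scale, while the normalisation behind it is not given in the sources used here. That table served as an alternative.

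Each array had 22176 spots, of which 20460 were chicken oligonucleotide probes, 1480 were empty, 218 were human negative controls and 18 were control oligonucleotides. A gene symbol was given in the files for 6149 probes (5557 genes), a locus number alone for 6980, a cDNA clone alone for 4772, another description for 121 and none for 2438. Symbols are those of the array design and can be old. Turkey RNA was hybridised to chicken sequence, so a mismatch lowers a probe's signal in all groups alike, and levels of different probes were not compared. Probes present on at least 5 arrays were tested, 18012 in all, of which 5690 carried a symbol (5204 genes). For the 400 genes with more than 1 tested probe, the brightest probe stood for the gene, and none of the genes chosen by the rule for named genes had a second tested probe.

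Within-array log2 ratios were normalised by loess (span 0.3, 4 iterations), with empty and control spots left out. They were fitted with limma 3.58.1 in R 4.3.3 by a model with the 3 groups and a dye intercept over all 6 arrays, so that each comparison used its direct arrays and the path through the third group. Moderated two-sided tests had 2 to 3 residual degrees of freedom and 6.64 prior degrees of freedom, with a prior SD of 0.194. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and every adjusted p below comes from limma. Those of probes were adjusted over all tested probes, and those of gene lists over the 22 lists tested in a comparison. Standard errors (SE) are those of the moderated fit. The median SE of a log2 fold change was 0.11, and the number of arrays limits the precision.

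Per-pool levels are normalised log2 intensities, rebuilt from each array's normalised ratio and mean, and a level therefore carries the brightness of its spot on that array while a ratio does not. Gene lists for pathways and cell types were tested with limma's camera at a preset correlation of 0.01, with 1 probe per named gene, where at least 5 members were measured. Members were also adjusted over the list alone, which does not correct for the number of lists. Camera with an estimated correlation and fry were run beside it. The lists covered monoamine and melatonin synthesis, the circadian clock, photoreception, the thyroid photoperiod pathway, reproductive neuropeptides, neurosteroid synthesis, immediate early genes, GABA and glutamate, synaptic vesicles, voltage-gated channels, heat shock and chaperones, cholesterol synthesis, retinoid signalling, ribosomal proteins, oxidative phosphorylation, proteasome and histones. Marker lists covered myelin and oligodendrocytes, astrocytes and tanycytes, microglia and immune cells, endothelium and mural cells, red blood cells, choroid plexus and ependyma, pituitary and neurons.

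The groups, the design, the lists and the rule for named genes were fixed before the data were examined. Where under 10 named genes passed in a comparison, the rule took all that passed, and the 5 highest and 5 lowest log2 fold changes at an unadjusted p under 0.01 with both direct arrays in that direction. It added up to 4 members of each list that passed over the list alone, and a fixed set of clock, opsin, monoamine and hormone genes. A gene that the rule chose is not reported here. The latter set's TPH1, TPH2, AANAT, PER3, CRY2, OPN5, GNRH1, TSHB, CGA, DIO3 and FOS had no tested probe and were not analysed here.

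Alternatives covered the background, the normalisation, a filter on dim probes, the dye term, array weights, separate channels with and without the replicate number, direct arrays alone, the authors' value table and each array left out. Keeping all spots, keeping only complete probes and adding an offset of 50 to both channels were added after the data were seen. The steps were tested on simulated data over 18012 probes for each comparison. For LDPS against SDPS, 68.7% of changes of 0.5 on the log2 scale and 100% of changes of 1 were recovered, with 6.77% false calls. The shares were 67.2% and 100% for LDPR against LDPS, with 9.14% false calls. They were 58.2% and 98.5% for LDPR against SDPS, with 6.56% false calls. The simulated noise was normal and independent between probes, at the moderated spread of the fit and with no missing spots. Real data can depart from this, so the shares do not show that changes of these sizes are absent where no probe passed.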

Results

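Transcript levels were measured in the premammillary nucleus of turkey hens, a dopamine-melatonin cell group of the avian hypothalamus that has been linked to the reading of day length. SDPS hens were kept at 6 h light and 18 h dark, and LDPS hens received 16 h light and 8 h dark for 10 days. LDPR hens were held on long days through a reproductive cycle and moult, and the hours of their schedule are not given in the sources used here. Each group had 4 pools of 6 hens. Median spot amplitudes ranged from 92.65 to 276.5 over the channels, and the signal-to-background ratio from 5.12 to 12.92. Between 91.6% and 96.6% of probes lay above the 95th percentile of empty spots in the other channels, against 79.3% in LDPR pool 2. Pooling hides the spread between hens, so p-values measure the spread between pools, which cannot be told apart from that between arrays. The moderated fit also borrows part of this spread from other probes.

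The first comparison asked what 10 long days changed in hens still able to respond to light. Galanin (GAL), a neuropeptide, was lower in LDPS than in SDPS, with a log2 fold change of -1.02 (SE 0.11) and the direct array nearest 0 at -0.95. Oestrogen receptor beta (ESR2) was lower by -0.97 (SE 0.16), and NPVF, the precursor of gonadotropin-inhibitory hormone, by -0.74 (SE 0.23). The haemoglobin genes HBG2 and HBA1 were higher, at 0.71 (SE 0.13) and 0.66 (SE 0.15). None of these passed over all probes, with an adjusted p of 0.0832 for GAL, 0.519 for ESR2 and 0.854 for HBG2. Over the alternatives the adjusted p of GAL ran from 0.000254 with separate channels to 1 without a dye intercept.

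GAL averaged 10.2 ± 0.18 in SDPS and 9.14 ± 0.36 in LDPS (log2 intensity, SD, n = 4 each), and the ranges of the pools did not overlap. ESR2 averaged 7.20 ± 0.36 and 6.11 ± 0.09 (SD, n = 4 each). Among other named genes that did not pass, ITGB2, a leukocyte integrin chain, had a log2 fold change of 0.60. The potassium channel gene KCNN2 and the sphingomyelinase gene SMPD4 were both at 0.53. On the lower side C7ORF16 was at -0.57 and the neuronal transcription factor gene ISL1 at -0.49.

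Of the 30 measured reproductive neuropeptide genes, 20 had negative values and the list was shifted down (median -0.08, adjusted p = 2.6e-05; adjusted p = 0.392 with an estimated correlation). GAL and ESR2 fell when adjusted over the list alone, with adjusted p-values of 0.000139 and 0.00216. INHBA (-0.27), CPE (-0.23) and PRLR (-0.24) did not pass. Of 44 ribosomal protein genes, 39 were negative (median -0.11, adjusted p = 2.69e-05; adjusted p = 0.558 with an estimated correlation), with array medians of -0.21 and 0.01. Of 14 astrocyte and tanycyte markers, 10 were negative (median -0.12, adjusted p = 0.0312; adjusted p = 0.392 with an estimated correlation). Among them the glutamate transporter SLC1A3 (-0.34) and the water channel AQP4 (-0.27) did not pass over the list alone. Of the 4 measured red blood cell genes, HBG2, HBA1 and HBZ (0.23) rose when adjusted over the list alone, and 0 passed over all probes. RAB3B (-0.43), a synaptic vesicle gene, fell and FSHB (0.50), the follicle-stimulating hormone beta chain, rose when each was adjusted over its list alone.

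The dopamine enzyme gene TH had a log2 fold change of 0.23 (SE 0.10, unadjusted p = 0.0372) and did not pass. The clock genes PER2 (0.23), CRY1 (0.19), ARNTL (-0.21) and CLOCK (0.05) did not pass, nor did OPN4 (0.15), DIO2 (-0.06), VIP (0.15), POMC (-0.14), PRL (-0.01) or ASMT (-0.11). The circadian clock list (median -0.01, adjusted p = 0.78) and the monoamine and melatonin list (median 0.09, adjusted p = 0.129) were not called. The photoreception list had a median of 0.06 (adjusted p = 0.209) and the thyroid photoperiod list a median of 0.00 (adjusted p = 0.78).

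By limma, 0 of 18012 probes passed for LDPS against SDPS, and 780 had an unadjusted p under 0.05 (545 higher, 235 lower) where chance gives 901. With 1 array left out, the count at unadjusted p ran from 461 (without LDPS pool 3 and LDPR pool 3) to 1691 (without LDPS pool 2 and SDPS pool 2). It was 365 without a dye intercept. The separate-channel fit called 5 probes. Without the array of SDPS pool 1 and LDPS pool 1, 0 lists were called, with an adjusted p of 0.0897 and a median of -0.02 for the neuropeptides and 0.297 with a median of -0.05 for ribosomal proteins. The astrocyte call was lost in 5 of the 6 fits without 1 array (adjusted p from 0.0552 to 0.294, medians from -0.12 to -0.15), and the ribosomal call also without LDPR pool 2 and SDPS pool 4 (adjusted p = 0.0747, median -0.09). Under median centring neither was called (adjusted p = 0.126 each, medians -0.06 for ribosomal proteins and -0.08 for astrocytes), and the neuropeptide median was -0.03.

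**Figure D1:**
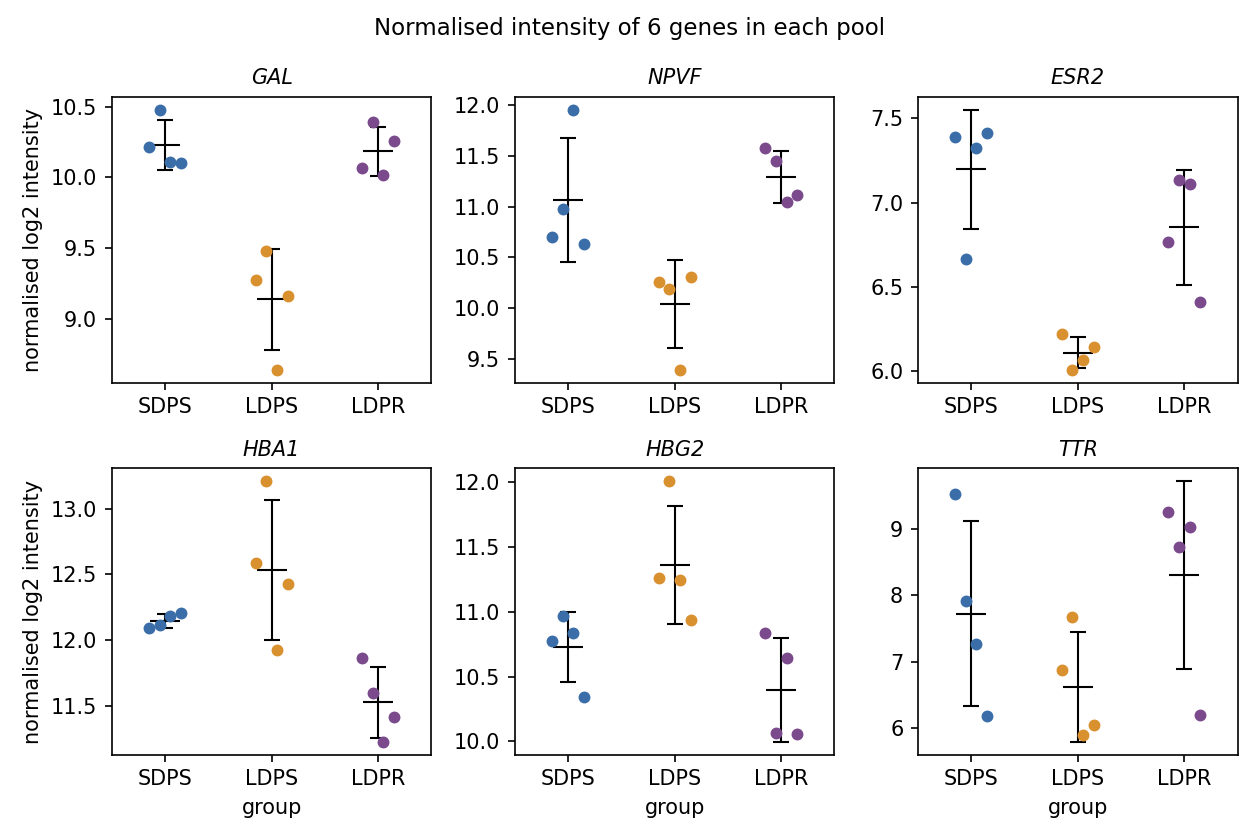
Normalised log2 intensity (vertical axis) of GAL, NPVF, ESR2, HBA1, HBG2 and TTR in each pool of SDPS, LDPS and LDPR hens; points are pools, horizontal bars the means and whiskers the SD (n = 4 per group). GAL lay between 8.64 and 9.48 in the LDPS pools, below the lowest SDPS pool (10.1) and the lowest LDPR pool (10.0).

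The second comparison set photorefractory against photosensitive hens, both on long days. GAL rose in LDPR by a log2 fold change of 1.19 (SE 0.11, 2.28-fold, adjusted p = 0.0129), and both direct arrays were above 0 (1.38 and 1.10). GAL averaged 10.2 ± 0.17 in LDPR against 9.14 ± 0.36 in LDPS (log2 intensity, SD, n = 4 each). NPVF was higher by 1.09 (SE 0.23) but did not pass (adjusted p = 0.148). HBA1 and HBG2 were lower, at -0.99 (SE 0.15) and -0.80 (SE 0.13), and did not pass either (adjusted p = 0.102 and 0.139). Without the array of LDPS pool 2 and SDPS pool 2, HBA1 passed at -0.84 (adjusted p = 0.0283).

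The other 2 of the 3 probes that passed carried no gene symbol and were named after their values were seen. RIGG13871, which has no description, was lower by -1.04 (SE 0.10, adjusted p = 0.0129), and was above the empty-spot level in 3 of the 4 LDPR channels. With an offset of 50 added to both channels it was at -0.46 and did not pass (adjusted p = 0.0794). RIGG02307, described only as a cDNA clone, was higher by 0.92 (SE 0.10, adjusted p = 0.0232). RIGG02307 was at 0.90 (adjusted p = 0.0732) with LDPR pool 2 and SDPS pool 4 left out, and at 0.84 (adjusted p = 0.0624) under median centring. Named genes that did not pass included TTR, the thyroid hormone carrier transthyretin, at 2.33 (SE 0.60), with direct arrays at 3.13 and 0.16. Without LDPR pool 4 and LDPS pool 4, TTR passed at 3.78 (adjusted p = 0.00382). ARMC1 (0.71), METTL8 (0.68) and the muscle troponin gene TNNI1 (0.63) were higher, and ARMC1 was above the empty-spot level in 2 of the 4 LDPS channels. ITGB2 (-0.76), the homeobox gene PAX6 (-0.74) and FSHB (-0.73) were lower, and FSHB was above the empty-spot level in 3 of the 4 LDPR channels.

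Of 24 heat shock and chaperone genes, 21 were positive and the list was shifted up (median 0.20, adjusted p = 1.21e-05; adjusted p = 0.664 with an estimated correlation). Among its members HSPA5, the main chaperone of the endoplasmic reticulum, was at 0.38, HSP90B1 at 0.32 and HSP70 at 0.31, and 0 passed when adjusted over the list alone. Of 30 reproductive neuropeptide genes, 18 were positive (median 0.08, adjusted p = 0.00433; adjusted p = 0.664 with an estimated correlation). GAL, NPVF and ESR2 (0.60) rose when adjusted over the list alone, and GAL alone passed over all probes. Of 44 ribosomal protein genes, 36 were positive (median 0.08, adjusted p = 0.0245; adjusted p = 0.709 with an estimated correlation), and under median centring the list median was -0.03 (adjusted p = 0.907). Without LDPS pool 3 and LDPR pool 3, the neuropeptide list had an adjusted p of 0.0753 with a median of 0.075, and its medians ran from 0.02 to 0.14 over the fits without 1 array. The ribosomal call was lost in 4 of the 6 fits without 1 array (adjusted p from 0.0765 to 0.302, medians from 0.03 to 0.09).

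Single members of other lists passed when adjusted over the list alone. None of them passed over all probes, with adjusted p-values from 0.102 for HBA1 to 0.183 for TRH and STRA6. DBH (-0.42), the enzyme that makes noradrenaline, INSIG2 (-0.48), STRA6 (-0.42), ITGB2 and FSHB fell, as did HBA1 and HBG2 among 4 red blood cell genes. TRH (0.49), RAB3B (0.53) and the astrocyte transporter SLC1A3 (0.37) rose. TTR rose within the thyroid, retinoid and choroid plexus lists; its levels ran from 5.90 to 9.53 over the 12 pools, and the other choroid plexus markers FOLR1 (0.06) and TEKT1 (0.27) did not pass. TH (0.00), CRY1 (0.22), PER2 (0.09), ARNTL (0.17), CLOCK (-0.18), VIP (-0.33), DIO2 (-0.15), POMC (0.09), PRL (-0.18), ASMT (0.01) and OPN4 (-0.08) did not pass over all probes.

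At unadjusted p under 0.05 there were 2511 probes (893 higher, 1618 lower) for LDPR against LDPS, where chance gives 901. With 1 array left out this number ran from 1190 (without LDPS pool 3 and LDPR pool 3) to 2616, and it was 1246 without a dye intercept. None of the 3 calls was kept when the array of LDPS pool 1, LDPR pool 1, LDPR pool 3 (quantified on a later date than the other arrays) or LDPR pool 4 was left out, where GAL had adjusted p-values of 0.106, 0.0563, 0.695 and 0.0663 and log2 fold changes of at least 1.07. The count was 0 without a dye intercept, with direct arrays only and with all spots kept, 18 with print-tip loess, 31 with scaling between arrays and 560 with separate channels.

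**Figure D2:**
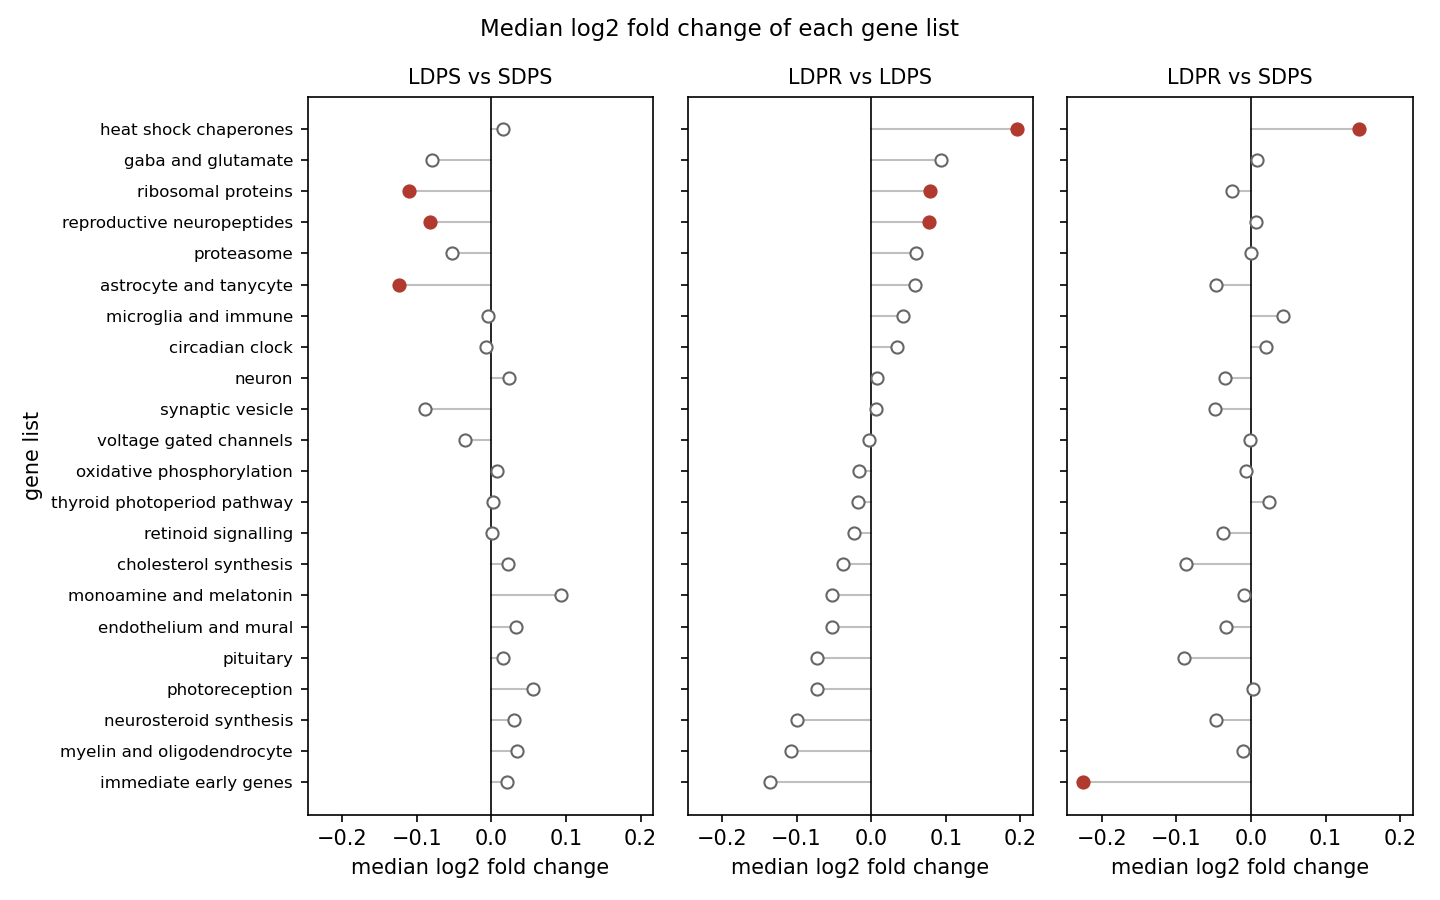
Median log2 fold change (horizontal axis) of the 22 tested gene lists (vertical axis) in each comparison; filled points passed camera with a preset correlation, and open points did not. The heat shock and chaperone list had medians of 0.02, 0.20 and 0.15 from left to right. The ribosomal median for LDPR against LDPS was -0.03 under median centring.

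The third comparison set photorefractory hens against short-day photosensitive hens. METTL8 was higher in LDPR by a log2 fold change of 0.79 (SE 0.13) and TNNI1 by 0.73 (SE 0.10). UTS2, the precursor of the peptide urotensin 2, was lower at -0.80 (SE 0.24), and the ubiquitin-conjugating enzyme gene UBE2E1 at -0.75 (SE 0.21). None passed over all probes, with adjusted p-values of 0.355, 0.286, 0.411 and 0.411 in that order. NPVF was at 0.35 (SE 0.23), with direct arrays at -0.38 and 0.81.

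Further named genes that did not pass were C1QTNF7 (0.67), PHF20L1 (0.55) and HSPA5 (0.54) on the higher side. CRSP3 (-0.64), GLT8D3 (-0.61) and SNX30 (-0.57) were on the lower side, and SNX30 was above the empty-spot level in 1 of the 4 LDPR channels. TH was at 0.23 (unadjusted p = 0.0356) and CRY1, a repressor of the circadian clock, at 0.41 (unadjusted p = 0.00525), and neither passed over all probes. PER2 (0.32), ARNTL (-0.04), CLOCK (-0.13), VIP (-0.18), DIO2 (-0.22), POMC (-0.05), PRL (-0.19), ASMT (-0.11) and OPN4 (0.07) did not pass.

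Of 24 heat shock and chaperone genes, 21 were positive (median 0.15, adjusted p = 8.82e-08; adjusted p = 0.962 with an estimated correlation). HSP90B1 (0.53), HSPA5 and DNAJA1 (0.37) rose when adjusted over the list alone, and 0 members passed over all probes. Of 13 immediate early genes, which neuronal activity induces quickly, 10 were negative (median -0.22, adjusted p = 0.0128; adjusted p = 0.966 with an estimated correlation). BTG2 (-0.57) fell when adjusted over the list alone, while EGR1 (-0.37) and DUSP1 (-0.26) did not pass. OPN1LW (-0.52) of the photoreception list and INSIG2 (-0.43) of the cholesterol list fell when adjusted over their lists alone. BTG2 and OPN1LW were above the empty-spot level in 2 of the 4 LDPR channels. LDPR pool 2, in which fewer probes lay above the empty spots (79.3%), shared its array with SDPS pool 4.

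By limma, 0 of 18012 probes passed for LDPR against SDPS, 1687 had an unadjusted p under 0.05 (626 higher, 1061 lower) where chance gives 901, and separate channels called 50. The 1687 became 1023 without LDPR pool 2 and SDPS pool 4, 2871 without LDPS pool 2 and SDPS pool 2, and 614 without a dye intercept. Without the array of LDPR pool 2 and SDPS pool 4, the immediate early list had a median of -0.03 (adjusted p = 0.578), and without that of LDPS pool 2 and SDPS pool 2 the fit called 4 probes. Camera did not call the immediate early list with separate channels either (median -0.24, adjusted p = 0.0628). Nor was it called when the replicate number was added to them (median -0.12, adjusted p = 0.7) or with all spots kept.

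Over any difference among the 3 groups, GAL (adjusted p = 0.0403) and RIGG13871 (adjusted p = 0.0482) passed, and 1936 probes had an unadjusted p under 0.05. The GAL level was lowest in LDPS, and SDPS and LDPR differed by a log2 fold change of 0.17 (adjusted p = 0.653). The direct ratios of the 3 pairs of groups, taken from different pools, were added around the loop, where they should cancel: by limma 0 probes departed from closure and 594 had an unadjusted p under 0.05, where chance gives 901. Across 18012 probes, which are not independent replicates, the direct ratios correlated at -0.197 (LDPS against SDPS with LDPR against LDPS), -0.151 (LDPS against SDPS with LDPR against SDPS) and 0.303 (LDPR against LDPS with LDPR against SDPS).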

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

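The tests of a single array, tissue boundaries, blood, stress at sampling, brightness of the chaperone list, the array quantified later and splits by shared array were chosen only after the result was seen; counts of splits and brightness of single genes were fixed earlier.

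GAL, NPVF and ESR2 were lower in LDPS than in SDPS, and none of them passed over all probes. A single array could not account for GAL, since the log2 fold change nearest 0 with 1 array left out was -0.949. A bias that follows brightness stays open: at most 1% of the 200 probes of nearest brightness reached as large a change (0% for NPVF and ESR2), but the genes were picked as extremes, so few neighbours would reach them in any case. Different boundaries of the dissected tissue also stay open. AVP, a peptide gene of neighbouring nuclei, was at -0.083 (SE 0.13) against -0.744 (SE 0.226) for NPVF, and their intervals overlapped at the bound set for this test. AVP is also bright enough to hide a small shift. A response of these genes to long days stays open as untested.

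HBA1 and HBG2 were highest in LDPS. A bias that follows brightness stays open here too, since at most 0.5% of the 200 nearest probes reached as large a change but both genes were picked as extremes. More blood in the LDPS pools could account for both genes, but the test did not decide: their deviations from group means correlated over 12 pools at r = 0.512 (permutation p = 0.206) and rho = 0.329 (permutation p = 0.368), 1 relation tested with 100000 resamples. Without the 2 pools farthest out, r was 0.217. The resampling moved pools within groups without regard to the array they shared, so its p-values are only approximate. A change in blood supply with day length stays open as untested.

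At a preset correlation the heat shock and chaperone list was called higher in LDPR than in both other groups, and both calls were lost with an estimated correlation (adjusted p = 0.664 against LDPS and adjusted p = 0.962 against SDPS). A bias that follows brightness was argued against for the comparison with SDPS. The medians of 10000 lists of like brightness centred at 0.005, against 0.145 for this list. The list median lay at percentile 100 of them, but the list was picked because it was called, so this percentile does not measure chance. The array quantified on a later date, that of LDPS pool 3 and LDPR pool 3, did not carry the preset call against LDPS alone (adjusted p = 0.0305 and median 0.13 without it). Without it the 3 probe calls for LDPR against LDPS ended (adjusted p = 0.695 each). Their log2 fold changes stayed at 1.07 for GAL, 0.90 for RIGG02307 and -0.965 for RIGG13871. The probes at unadjusted p under 0.05 fell to 1190 without that array. Without the other direct array, that of LDPR pool 4 and LDPS pool 4, there were 2022, and GAL had an adjusted p of 0.0663. How far the 3 probe calls rest on the array quantified later was therefore not settled. Stress or delay at sampling cannot be told apart from the group: the immediate early list ran from a median of -0.22 on all arrays to -0.027 without LDPR pool 2 and SDPS pool 4, and the bound was tightened after this value was known. A state of the refractory hens may also underlie it, untested.

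For LDPR against LDPS, 1 of the 34 splits that could be fitted, the real one, gave as many genes (3, highest other 1). Only 12 of these splits set the pools of every array in different groups, as the real one does (highest other 0), which is too few for a share under 0.05. At unadjusted p, 3 of 34 splits gave as many probes (2511, highest other 3385), and among the 12 splits the highest other was 1832. For lists 11 of 34 splits gave as many (3, highest other 4), so chance was not excluded for probes or lists. For LDPS against SDPS, 19 of 34 splits gave as many probes (780, highest other 2013) and 3 as many lists (3, highest other 3), and for LDPR against SDPS 6 gave as many probes (1687, highest other 3086) and 16 as many lists (2, highest other 4), so chance was not excluded. Both had 0 genes, which all 34 splits reach whatever the data (highest other 8 and 51), so these counts decide nothing. For any group, 5 of 100 drawn splits gave as many genes (2, highest other 43), and chance was not excluded. Among the 25 drawn splits that set the pools of every array in different groups the highest other was 1, and the split with 43 genes was not among them. For the pairs, the splits with 8 and 51 genes did set the pools of every array in different groups. Large counts thus also arose without a shared array within a group, and a structure by shared array was not settled.

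Single pools stood apart from the other 3 of their group in 12 of 163 groups tested, and chance gives such a gap in about 5% of groups. In log2 intensity, KCNN2 was 7.85 in LDPR pool 3 (others 8.88 to 9.07), ESR2 was 6.67 in SDPS pool 2 (others 7.32 to 7.41) and NPVF was 9.39 in LDPS pool 3 (others 10.19 to 10.31). The other pool of the array was also the lowest of its group for ESR2 (6.01) and NPVF (11.04), but not for KCNN2 (8.645). In LDPR pool 4, RAB3B was 7.9, TRH was 6.66 and PHF20L1 was 7.22. LDPS pool 4, on the same array, was the most extreme of its group in the same direction (7.62, 6.22 and 6.69). ARMC1 was 5.51 in SDPS pool 2, and METTL8 was 9.82 in LDPR pool 3. Their array partners, LDPS pool 2 (5.64) and LDPS pool 3 (9.32), were likewise the highest of their group. HSP90B1 was 11.81 in SDPS pool 2 (others 8.96 to 9.13), and LDPS pool 2 on the same array stood at 12.1. The ribosomal mean was 11.63 in LDPS pool 2 (others 11.18 to 11.2), and the immediate early mean was 7.51 in LDPR pool 3 (others 7.08 to 7.09). In SDPS pool 4, 91.6% of probes lay above the empty spots (others 95.3% to 95.7%).

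Spots outside the comparisons carried signal. Of 18 control oligonucleotides, 15 exceeded the empty-spot level in every channel. Of the values of the 218 human negative control spots, 28.4% exceeded it, with 15.6% to 44% per channel, against 5% for the empty spots by construction.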

How the results depend on the processing

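Tests that kept all spots, kept only complete probes or added an offset of 50 were chosen only after the result was seen, and the others were planned. The confidence threshold of the reported fit was not in the design either. With all spots kept, GAL had an adjusted p of 0.212 for LDPR against LDPS. In the order LDPS against SDPS, LDPR against LDPS, LDPR against SDPS and any group, probes that passed (0, 3, 0 and 2) became 1, 18, 0 and 6 with print-tip loess. They became 1, 31, 1 and 8 with scaling between arrays and 5, 560, 50 and 261 with separate channels, which tested 16748 probes. They were 0 throughout without a dye intercept and with all spots kept, and 0 for each pair with direct arrays only, where the test over any group was not run. Median centring gave 0, 2, 0 and 0. Array weights, the authors' value table and the offset of 50 each gave 1 probe for LDPS against SDPS, GAL each time (adjusted p = 0.0483, 0.0475 and 0.0105). GAL was also the probe called for that pair with print-tip loess and with scaling. With 1 array left out the counts ran from 0 to 0, 0 to 6, 0 to 4 and 0 to 11. Normexp with offset 0 and complete probes gave 3 probes for LDPR against LDPS, all shared with the 3 reported. The causes were not tested, except that fewer arrays leave fewer degrees of freedom. The filter on dim probes removed no tested probe and so tested nothing, a fit without background correction is the fit reported, and a date block was not possible because 1 array alone had the later date.

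Lists called (3, 3 and 2 over the pairs) were 0, 0 and 0 with an estimated correlation, 0, 0 and 1 with fry's directional test and 0, 9 and 1 with its mixed test. The directional call was the circadian clock (adjusted p = 0.0101), where 6 of 12 members were positive. Median centring left 1 for LDPS against SDPS and turned the ribosomal list for LDPR against LDPS to -0.032 (adjusted p = 0.907). All spots kept and separate channels each gave 1 for LDPR against SDPS, and the offset of 50 gave 5 for LDPS against SDPS. With 1 array left out the lists called ran from 0 to 4, 1 to 4 and 1 to 3. The estimated correlation was 0.329 for ribosomal proteins, 0.274 for immediate early genes and 0.171 for heat shock and chaperones. It was 0.0396 for astrocytes and tanycytes and 0.0322 for neuropeptides. All of these lay above the preset 0.01, so the preset calls assume less correlation than was estimated. What else made the list counts differ was not tested.

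With the replicate block in separate channels, 26, 1042, 13 and 548 probes and 1 list for LDPR against SDPS were called. The numbers did not pair the samples: 5 of 12 same-number pairs had r over 0.1 (-0.332 to 0.815), 4 of these pairs shared an array, and 8 of 12 samples matched their own number best. Those 8 were the samples of the 4 pairs that shared an array. Same-number pairs on different arrays ran from r = -0.332 to 0.14. Over named genes and alternatives, 1506 values kept direction and side of the threshold, 59 newly passed it, 24 no longer did, and 48 turned sign without passing in either fit. Over the called lists, 73 values kept both and 38 no longer passed. Averaging a gene's probes changed nothing, since no gene chosen by the rule had several. Around the loop, 0 probes departed from closure without a dye intercept and 160 had an unadjusted p under 0.05. Signal over background was 5.12 in LDPR pool 2, the lowest, which limits dim probes most there.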

Other observations

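By camera with a preset correlation, the lists in this paragraph were not called in any comparison on all 6 arrays, and the values here are for LDPR against LDPS. Lists of transmitter genes had medians of 0.09 for GABA and glutamate (adjusted p = 0.214), 0.01 for synaptic vesicles (0.551), 0.00 for voltage-gated channels (adjusted p = 0.892) and -0.05 for monoamine and melatonin (0.639). Among pathways, neurosteroid synthesis stood at -0.10 (adjusted p = 0.214), cholesterol synthesis at -0.04 (0.248), retinoid signalling at -0.02 (0.758), oxidative phosphorylation at -0.02 (0.697) and the proteasome at 0.06 (0.214). Photoreception stood at -0.07 (adjusted p = 0.426), the thyroid photoperiod list at -0.02 (0.551) and the circadian clock at 0.03 (0.639). Of 4 measured histone genes, 2 were positive. Without LDPR pool 4 and LDPS pool 4, camera called the thyroid photoperiod list up for LDPR against LDPS (adjusted p = 0.000322) and against SDPS (adjusted p = 0.00115). This list holds TTR, which passed against LDPS in that fit, and on all arrays 5 of its 12 members were positive for LDPR against LDPS. The same fit had GABA and glutamate and synaptic vesicles called down for LDPS against SDPS (adjusted p = 0.047 each). With the offset of 50 camera called these 2 transmitter lists down as well (adjusted p = 0.0471 and 0.0348). Without LDPS pool 2 and SDPS pool 2 it called the proteasome down for LDPS against SDPS (adjusted p = 0.0137) and up for LDPR against LDPS (adjusted p = 0.04). Fry's mixed test, which asks for changes in either direction and does not compare a list with other genes, called for LDPR against LDPS GABA and glutamate, voltage-gated channels, monoamine and melatonin (adjusted p = 0.0181 each), synaptic vesicles (adjusted p = 0.0364) and cholesterol synthesis (adjusted p = 0.0408). For LDPR against SDPS it called monoamine and melatonin (adjusted p = 0.0366), and fry's directional test called the circadian clock (adjusted p = 0.0101). Of the 12 measured clock genes, 6 were positive and 6 negative in that comparison. Their median was 0.02, and camera gave an adjusted p of 0.702, so no common shift was seen.

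Camera called no marker list of other cell types for LDPR against LDPS either, while fry's mixed test called astrocytes and tanycytes (adjusted p = 0.0181) and pituitary (adjusted p = 0.0408). Medians were -0.11 for myelin and oligodendrocytes (adjusted p = 0.223), -0.05 for endothelium and mural cells (0.697), 0.04 for microglia and immune cells (0.697), -0.07 for pituitary (0.288), 0.01 for neurons (0.738) and 0.06 for astrocytes and tanycytes (0.214). In the uncalled thyroid, retinoid, microglia, oxidative phosphorylation, neuron and voltage-gated channel lists the median, mean and test differed in sign for this comparison. They differed for LDPS against SDPS in the immediate early, cholesterol, microglia, clock, thyroid, retinoid and voltage-gated channel lists. For LDPR against SDPS they differed in the endothelium, GABA and glutamate, monoamine, neuron, oxidative phosphorylation, photoreception, proteasome, neuropeptide, retinoid and voltage-gated channel lists.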
